A study of Mus musculus with 8 samples.

How the data were processed

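Faecal samples of female C57BL/6 mice were measured, 4 untreated and 4 collected 24 h after 20 mg of streptomycin by gavage. Per the labels, faeces were extracted with acetonitrile, and the extracts were infused into a Fourier-transform ion cyclotron resonance instrument over m/z 150 to 1100, in positive and in negative ion mode, with 2 acquisitions per sample and mode, 200 scans per spectrum and an internal calibrant mix. Per the labels, mass accuracy was within 2 ppm. The authors deposited 1 table of relative intensities, on a linear scale, per neutral mass and acquisition. What the intensities are relative to, and how peaks were picked, aligned and joined across ion modes, is not given in the sources used here. The deposited column descriptions call the table unfiltered, but each group lists a mass in none or in 6 to 8 of its 8 acquisitions, and in no case in 1 to 5.

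The table does not say which ion mode a row came from, and 49 masses stand on 2 rows. The planned fits per mode could therefore not be run as written, and all rows were fitted together. For the same reason every row within 3 ppm of a listed formula was taken as a match, in place of the nearest row in each mode; the nearest row alone was run as an alternative. Of 199 formulas in 18 lists, 107 were matched by 142 masses, against a mean of 4.7 and at most 17 formulas over 20 sets of shifted decoy masses. The median absolute error of the matches was 0.284 ppm. The shifted decoys do not count matches to another ion form or compound at the same mass. A match is a formula and not an identification.

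The mean of both acquisitions, with 0 for an acquisition that did not list the mass, was the value of a sample. Values were log2 transformed after 0 was set to the lowest intensity of the table, 0.0738. Masses listed in at least 3 samples of a group were tested, which all 2429 were. The main test was limma's lmFit and eBayes over the 4 untreated and 4 streptomycin samples without a replicate block, with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists with at least 3 matched masses were tested with camera at a preset correlation of 0.01, and the adjustment ran over these 14 lists. Ratios of group means were taken over masses listed in both groups. Masses and total intensity per sample were compared by exact two-sided permutation tests, whose smallest p with 4 against 4 samples is 0.0286. Errors given are SDs over samples or SEs from limma. Log2 changes of masses listed in one group only depend on the value put in for 0 and are not reported.

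The lists, the tests, the rule for the masses named in the text and the main set of alternatives were fixed before the data were examined. The rule named up to 3 changed masses per list with the largest log2 change, the 3 masses with the largest change in each direction whose groups do not overlap, and in every case the formulas of taurocholic, cholic and deoxycholic acid, corticosterone, prostaglandin E2, hexaric acid, hexitol, stercobilin, equol, linoleic acid, indoleacetic acid and streptomycin. Other list members in the text serve as examples and were chosen after their values were seen.

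Alternatives were other values for undetected masses, other detection filters, division by total intensity or by the median ratio, an intensity trend, the methods' t-test, a replicate block, single acquisitions, leaving out each sample, and other tolerances, ion forms and set tests for the lists. Scaling to the 2 calibrant masses, the mean over listed acquisitions, merging of ion forms, a fit of the masses in both groups alone, and matching by the nearest row or the anion mass were added after seeing the data, as were counts of calls kept per direction on each scale and other tolerances for equal acquisitions. Rows were merged where they stood within 1 ppm of the spacing of a proton, sodium, potassium or hydrogen chloride and had intensities equal within 0.5% or were listed in opposite groups.

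The limma step was tested on simulated data drawn for 539 masses listed in all 8 samples, with 200 of them changed. It recovered 70% of the masses changed 2-fold and 98% of those changed 4-fold, with 6 false calls among 174. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, pyteomics 5.0.1, networkx 3.6.1 and matplotlib 3.10.9.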

Results

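Faecal extracts of female C57BL/6 mice, an inbred laboratory strain, were profiled by direct infusion into a Fourier-transform ion cyclotron resonance mass spectrometer, an instrument that weighs ions precisely enough to narrow down their elemental formulas but does not separate isomers. There were 4 samples from untreated mice and 4 samples collected 24 h after 20 mg of streptomycin, an aminoglycoside antibiotic that binds the bacterial ribosome, was given by oral gavage. The deposited table lists 2429 neutral masses with a relative intensity in each of 2 acquisitions per sample, and the mean of the 2 acquisitions was taken as the sample's value. Untreated samples listed 1210 to 1270 masses and had summed relative intensities of 19761 to 20140. Streptomycin samples listed 1633 to 1768 masses and had summed intensities of 21600 to 23221. The number of ions behind a relative intensity is unknown, so no counting interval can be given. Per the labels faeces were collected, mice were then treated and faeces were collected again, so treatment and time of collection cannot be separated. The labels do not say whether each sample came from a different mouse, so the p-values measure the spread between these samples, which may in part be technical. A metabolite name stands below for a mass within 3 ppm of the neutral formula of that metabolite, and isomers share the name.

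The comparison asked how a single antibiotic dose changed the small molecules of the gut contents. Of 15 masses with the formulas of unconjugated bile acids 9 were lower after streptomycin and 2 were higher, and the masses of the bilirubin products urobilinogen and urobilin and of oleic acid were lower. All 9 masses of sugars, 12 of 14 masses of nucleosides, bases and vitamins, and 16 of 20 masses of plant polyphenols and saponins were higher, most of them listed at 0 in all 4 untreated samples. All 6 masses that matched conjugated bile acids as neutral formulas were higher, while other ion forms of them went both ways. The mass of cholic or muricholic acid, 408.2873 Da, was at 1658 ± 466 (SD, n = 4) in untreated and 229 ± 97.4 (SD, n = 4) in streptomycin samples. The mass of lysophosphatidylcholine 16:0, 495.3326 Da, was at 5.48 ± 2.09 and 55.6 ± 16.3 (SD, n = 4 each).

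Of the 2429 masses, 633 were listed in both groups, 646 in untreated samples only and 1150 in streptomycin samples only. The 1796 masses of one group only were 73.9% of the table, held 25.2% of the summed intensity of the untreated samples and held 52.8% of that of the streptomycin samples. Streptomycin samples listed 1711 ± 58.6 masses and untreated samples 1246 ± 25.8 (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest that 4 against 4 samples allow). Summed intensity was 19918 ± 161 in untreated and 22267 ± 693 in streptomycin samples, a log2 difference of 0.16 (SD, n = 4; exact permutation p = 0.0286). These sums and shares count every row, so an ion that stands on several rows may enter more than once. In streptomycin samples 314.0326, 349.0020 and 350.0092 Da stood at an equal 1105 each. In untreated samples 265.3004 and 287.2824 Da stood at 752 and 753. No sum was taken over merged ion forms, so how much of the difference and of the shares this makes is open. In the deposited values a group lists a mass either in none or in at least 6 of its 8 acquisitions. A 0 thus means that this level of detection was not reached, and no fold is given against a group listed at 0. After rows that stand at the spacing of another ion form were merged, a step chosen after the values were seen, 1522 masses remained in one group only. Of the 142 masses that matched a list, 15 have such a partner, 13 of them listed in the opposite group only.

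**Figure D1:**
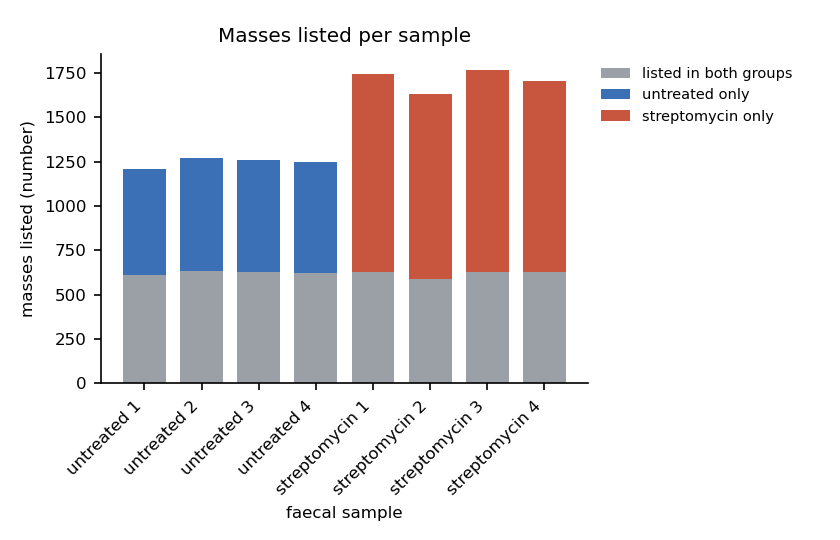
Number of masses listed (y axis) in each of the 8 faecal samples (x axis), stacked by whether a mass was listed in both groups, in untreated samples only or in streptomycin samples only. The 4 streptomycin samples list 1633 to 1768 masses and the 4 untreated samples 1210 to 1270.

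Among the 633 masses listed in both groups, 376 differed (limma, adjusted p under 0.05), 131 of them higher and 245 lower in streptomycin samples. A ratio of group means of at least 2 was found for 282 of the 633 masses, 86 higher and 196 lower. After scaling to the calibrants these counts were 46 higher and 279 lower, and after division by total intensity 61 and 227. Over all 2429 masses limma called 2172, 1281 higher and 891 lower, and every mass of one group only was among them because undetected values were set to the lowest intensity of the table. The 2 masses of the instrument calibrant, which was added to every extract, were also higher in streptomycin samples: 193 ± 21.7 against 147 ± 9.31 at 621.0216 Da, and 138 ± 12.4 against 100.3 ± 12.0 at 921.0027 Da (SD, n = 4). The balance of higher and lower calls followed the scaling: over the masses in both groups it was 65 higher and 321 lower after scaling to the calibrants, 103 and 287 after division by total intensity, and 190 and 177 after division by the median ratio. The median log2 change of these masses was -0.47 as deposited, -0.87 on the calibrant scale, -0.63 on the total-intensity scale and -0.08 on the median-ratio scale.

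Unconjugated bile acids, which gut bacteria release from the taurine and glycine conjugates secreted by the liver, were mostly lower. Of 15 masses matching 8 formulas, 9 were lower, 2 were higher and 4 did not pass; the counts adjusted over the list alone were also 9 and 2. For 2 of the lower masses, both of untreated samples only, a mass at an ion-form spacing was listed in streptomycin samples only: 410.2586 Da, at 18.7 ± 2.58, for oxo-cholanoic acid at 374.2821 Da, and 376.3189 Da, at 0.872 ± 0.240, for deoxycholic acid and its isomers at 392.2925 Da (SD, n = 4). The mass of cholic or muricholic acid changed by -2.90 ± 0.36 (log2, SE; limma adjusted p = 0.000104). Deoxycholic acid and its isomers, at 392.2928 Da, went from 319 ± 36.9 to 19.9 ± 3.84 (SD, n = 4; log2 change -4.02 ± 0.16 SE, adjusted p = 7.44e-08). The mass of lithocholic acid, 376.2979 Da, a bacterial product, was at 110.0 ± 29.97 (SD, n = 4) in untreated samples and listed at 0 in all 4 streptomycin samples. The masses of oxo-dihydroxycholanoic acid at 406.2718 Da and oxo-hydroxycholanoic acid at 390.2772 Da changed by -2.67 ± 0.54 and -3.68 ± 0.45 (log2, SE). A second mass of several of these formulas did not pass: 408.2876 Da was at 14.6 ± 3.47 and 10.1 ± 5.76 (adjusted p = 0.165), and 390.2770 Da, also the formula of a common phthalate plasticiser, was at 174 ± 44.9 and 225 ± 23.5 (adjusted p = 0.0952). The list as a whole was lower by limma's camera test (adjusted p = 0.0321), but adjusted p = 0.497 with an estimated correlation and adjusted p = 0.0742 with adducts also matched.

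For conjugated bile acids all 6 masses matched as neutral formulas were higher (also 6 adjusted over the list alone), and 4 of them were listed in streptomycin samples only. Of other ion forms, the anion of taurocholic or tauromuricholic acid, 514.2838 Da, was at 218 ± 39.8 in streptomycin samples and listed at 0 in untreated samples. Masses at the chloride adducts of 2 taurine conjugates were lower: 551.2685 Da, of taurocholic or tauromuricholic acid, from 60.6 ± 10.0 to 22.3 ± 7.89, and 535.2736 Da, of taurodeoxycholic acid and its isomers, from 48.8 ± 6.44 to 18.7 ± 6.04 (SD, n = 4). Both have equal intensities to masses at the spacings of a proton and of hydrogen chloride, so they may be ions of other compounds. The mass of taurocholic or tauromuricholic acid, 515.2919 Da, was at 15.6 ± 1.55 (SD, n = 4) in streptomycin samples and at 0.718, 0.563, 0.311 and 0 in the untreated samples (limma adjusted p = 8.64e-05). Taurodeoxycholic acid and its isomers, at 499.2969 Da, were at 27.2 ± 10.4 and glycocholic acid, at 465.3091 Da, at 2.84 ± 0.494 (SD, n = 4), both listed at 0 in the untreated samples. The mass of cholic acid sulfate, 488.2444 Da, rose from 33.3 ± 11.7 to 85.5 ± 24.0 (log2 change 1.38 ± 0.29 SE, adjusted p = 0.00259), and it has equal intensities to masses at the same spacings, 487.2372 and 452.2678 Da, so the same doubt holds for it. The list's camera test gave an adjusted p = 0.0502, adjusted p = 0.359 with an estimated correlation, adjusted p = 0.238 over 10 masses with sodium and chloride adducts, and adjusted p = 0.0275 over 8 masses with anions. Of 4 matched masses of bile acid precursors and sterols, 3 were lower and 1 did not pass (camera adjusted p = 0.25). Dihydroxycholestanoic acid, an intermediate of bile acid synthesis at 434.3397 Da, went from 18.6 ± 5.74 to 2.68 ± 0.639 (log2 change -2.78 ± 0.28 SE). Stigmasterol, a plant sterol at 412.3705 Da, and trihydroxycholestanoic acid, at 450.3347 Da, changed by -0.47 ± 0.14 and -1.02 ± 0.29, and neither passed on the median-ratio scale.

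Of 4 matched bile pigments 2 were lower, both of them products that bacteria make from bilirubin. The mass of urobilinogen, 592.3263 Da, went from 133 ± 21.2 to 5.58 ± 1.73 (SD, n = 4; log2 change -4.61 ± 0.23 SE, limma adjusted p = 3.33e-07), and that of urobilin, 590.3104 Da, from 87.4 ± 19.01 to 9.11 ± 3.29 (log2 change -3.31 ± 0.29 SE, adjusted p = 1.16e-05). The other 2 did not pass: biliverdin, at 582.2479 Da, was at 1.28 ± 0.970 and 3.34 ± 0.825, and mesobilirubin, at 588.2949 Da, at 6.01 ± 0.967 and 4.13 ± 1.62. Mesobilirubin was lower past the threshold after division by total intensity (limma adjusted p = 0.0396) and on the calibrant scale (limma adjusted p = 0.00798). On the median-ratio scale it did not pass (limma adjusted p = 0.482). Bilirubin, stercobilinogen and stercobilin had no mass within 3 ppm. All 3 matched porphyrin and chlorophyll masses were higher. Pheophorbide a, a breakdown product of dietary chlorophyll at 592.2687 Da, went from 5.23 ± 1.26 to 23.4 ± 6.73 (log2 change 2.14 ± 0.28 SE, adjusted p = 0.000162). The masses of mesoporphyrin, at 566.2881 Da, and deuteroporphyrin, at 510.2264 Da, were each listed in 3 of the 4 streptomycin samples and no untreated sample, and 510.2264 Da lies closer to the sodium adduct of cholic acid sulfate (0.13 ppm) than to deuteroporphyrin (-0.599 ppm). The mesoporphyrin mass lies below its formula mass of 566.2893 Da by more than the stated accuracy of 2 ppm. Camera gave an adjusted p = 0.229 for bile pigments and an adjusted p = 0.494 for porphyrins.

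Lipids moved both ways. The most intense mass of the untreated samples, 280.2395 Da, lay 2.61 ppm below linoleic acid, outside the stated accuracy of 2 ppm. It was at 2044 ± 280 (SD, n = 4) in the untreated samples and listed at 0 in the streptomycin samples. The mass of oleic acid, 282.2555 Da, went from 1964 ± 203 to 328 ± 74.0 (log2 change -2.61 ± 0.18 SE, limma adjusted p = 2.23e-06), while that of palmitic acid, 256.2402 Da, went from 111 ± 6.81 to 195 ± 25.8 (log2 change 0.80 ± 0.12 SE, adjusted p = 0.000353). Linolenic acid was matched by 278.2244 Da in untreated samples only, at 39.5 ± 4.84, and by 278.2250 Da in streptomycin samples only, at 15.1 ± 1.96. Of 8 fatty acid masses, 2 were higher, 4 lower and 2 did not pass (camera adjusted p = 0.229). Of 13 masses of lysolipids, sphingoid bases and monoglycerides, 8 were higher, 4 lower and 1 did not pass (camera adjusted p = 0.513). Lysophosphatidylcholine 16:0, a membrane phospholipid that has lost 1 acyl chain, changed by 3.37 ± 0.34 (log2, SE; adjusted p = 2.93e-05). The 18:2, 18:1 and 18:0 forms, at 519.3326, 521.3481 and 523.3638 Da, were at 27.9 ± 11.2, 14.9 ± 5.40 and 17.5 ± 4.16 in streptomycin samples and listed at 0 in untreated samples. For the 18:1 and 18:0 forms a mass lower by the spacing of sodium for hydrogen, 499.3664 and 501.3817 Da, was listed in untreated samples only, at 3.70 ± 1.69 and 1.19 ± 0.455, so an ion form cannot be ruled out. Monolinolein, a product of fat digestion at 354.2770 Da, went from 226 ± 84.1 to 67.3 ± 14.5 (log2 change -1.71 ± 0.27 SE).

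Most sugar and nucleoside masses were listed in streptomycin samples and in no untreated sample. All 9 masses of sugars and sugar alcohols were found in streptomycin samples only, including hexitol, the formula of sorbitol and mannitol, at 4.40 ± 0.971 (182.0790 Da) and 3.31 ± 1.17 (182.0791 Da), disaccharide at 16.9 ± 4.73 (342.1162 Da), trisaccharide at 13.5 ± 2.21 (504.1691 Da) and N-acetylhexosamine, a unit of mucin glycans, at 20.1 ± 6.29 (221.0900 Da; SD, n = 4). Some masses at other ion forms of sugar formulas were listed in untreated samples too. The mass at the sodium adduct of hexonic acid, 218.0402 Da, was at 7.59 ± 1.73 in untreated and 10.0 ± 0.765 in streptomycin samples (SD, n = 4). That at the chloride adduct of tetrasaccharide, 702.1995 Da, was at 3.47 ± 1.65 and 6.13 ± 2.35. Its sodium adduct mass, 688.2039 Da, was in streptomycin samples only, at 0.820 ± 0.176. Of 14 masses of nucleosides, bases and vitamins, 12 were found in streptomycin samples only and 2, retinol and tocopherol, did not pass. Cytidine was at 7.40 ± 0.652 (243.0856 Da), uridine at 6.93 ± 0.911 (244.0696 Da) and guanosine at 10.2 ± 1.57 (283.0918 Da; SD, n = 4). Counts adjusted over the list alone were the same, 9 and 12. Camera gave an adjusted p = 0.0357 for sugars (adjusted p = 0.359 with an estimated correlation) and an adjusted p = 0.00635 for nucleosides (adjusted p = 0.497 with an estimated correlation).

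Plant polyphenols and saponins of the diet were mostly listed in streptomycin samples only. Of 20 matched masses 16 were higher, 15 of them in streptomycin samples only, 2 were lower and 2 did not pass; over the list alone the counts were also 16 and 2. The soy isoflavones daidzein, with 2 rows at 254.0580 Da, and genistein, at 270.0529 Da, were at 24.3 ± 10.5, 19.3 ± 2.52 and 19.6 ± 2.10 in streptomycin samples and listed at 0 in untreated samples (SD, n = 4). Their glucosides daidzin, at 416.1107 Da, and genistin, at 432.1057 Da, were at 8.65 ± 1.66 and 6.16 ± 1.15 and likewise listed at 0 in untreated samples, as was soyasaponin I, at 942.5193 Da and 2.75 ± 0.196. The 2 lower masses were soyasapogenol B, the sugar-free core of these saponins, at 458.3759 Da and 1.27 ± 0.353 in untreated samples only, and 1 of the 2 masses of tricin. Camera gave an adjusted p = 0.0175, and adjusted p = 0.497 with an estimated correlation. Of the products that gut bacteria make from isoflavones, dihydrodaidzein, at 256.0736 Da, was at 6.09 ± 4.28 and O-desmethylangolensin, at 258.0893 Da, at 4.47 ± 2.37 in untreated samples, and both were listed at 0 in streptomycin samples. For O-desmethylangolensin a mass at the spacing of potassium for sodium, 242.1155 Da, was listed in streptomycin samples only, at 1.63 ± 0.195, so an ion form cannot be ruled out. Dihydrogenistein had 1 mass in untreated samples only, 272.0685 Da at 1.15 ± 0.190, and 1 in streptomycin samples only, 272.0687 Da at 0.840 ± 0.333. That list of 4 masses, 3 lower and 1 higher, had a camera adjusted p = 0.229. Equol had no mass within 3 ppm.

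**Figure D2:**
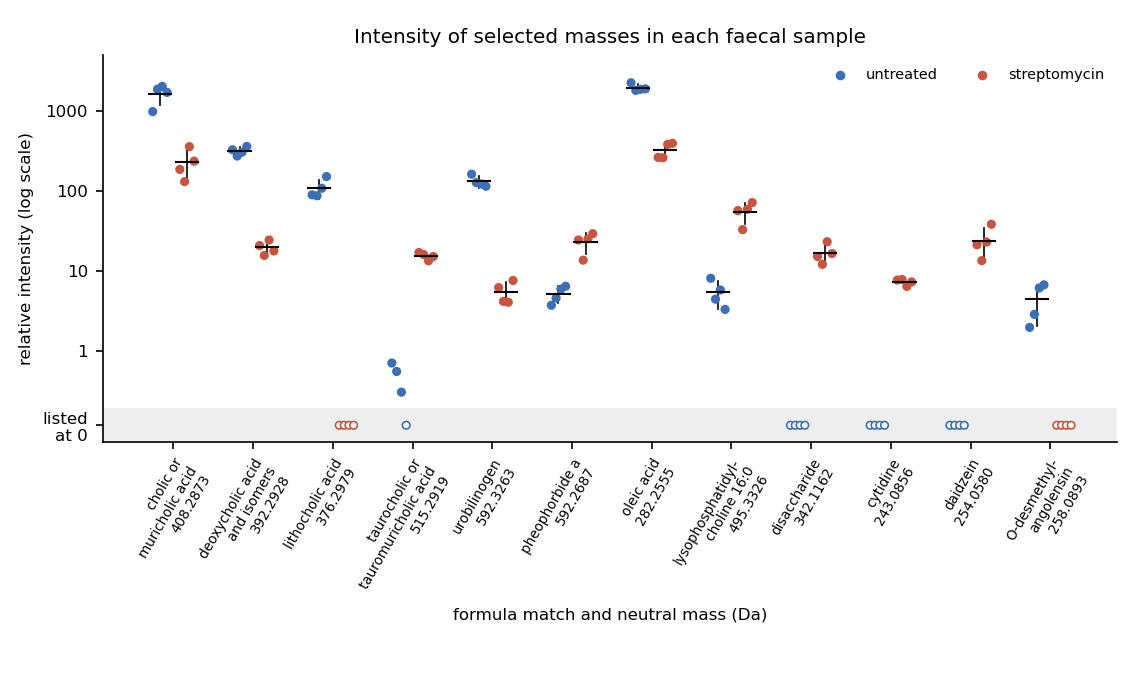
Relative intensity (y axis, log scale) of 12 masses (x axis; for each formula the matched mass with the highest group mean) in the 4 untreated and 4 streptomycin samples, 1 point per sample. Horizontal lines are means and vertical lines SDs where all 4 samples list the mass; open points in the grey band are samples listed at 0, as all 4 streptomycin samples are for lithocholic acid and all 4 untreated samples for cytidine.

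Steroid and eicosanoid formulas split between the groups. Of 14 steroid hormone masses 5 were higher, all in streptomycin samples only, and 9 lower (camera adjusted p = 0.229). For 4 of the 14, a mass at an ion-form spacing was listed in the opposite group only, so an ion form cannot be ruled out. Corticosterone, the main glucocorticoid of mice, at 346.2143 Da, was at 1.06 ± 0.0728 and 0.755 ± 0.197 (SD, n = 4; log2 change -0.53 ± 0.21 SE, limma adjusted p = 0.0402), but the call ended with the replicate block (adjusted p = 0.0750), on the median-ratio scale (adjusted p = 0.574), with the second acquisition alone (adjusted p = 0.187) and without any 1 of the untreated samples (adjusted p = 0.0608 to 0.0905). Tetrahydrocorticosterone, a reduced form, was listed in untreated samples only at 350.2458 Da, 6.18 ± 1.16, and fell by 1.38 ± 0.33 (log2, SE) at 350.2459 Da. The mass of progesterone, 314.2248 Da, was at 4.32 ± 0.284 in untreated samples only. Tetrahydrocortisol at 366.2408 Da was at 4.94 ± 1.58 in streptomycin samples only, while 366.2407 Da, of the same formula, was at 0.990 ± 0.0886 in untreated samples only. Of 19 eicosanoid and oxylipin masses 6 were higher, 8 lower and 5 did not pass (camera adjusted p = 0.229). The linoleate product hydroxyoctadecadienoic acid was at 20.7 ± 2.46 (296.2352 Da) in untreated samples only and went from 15.1 ± 2.49 to 6.42 ± 0.144 at 296.2353 Da, and arachidonic acid, at 304.2403 Da, was at 6.48 ± 0.857 in streptomycin samples only, with 282.2582 Da, at the same sodium spacing, at 8.43 ± 1.01 in untreated samples only. Prostaglandin E2 or D2 had 1 mass in untreated samples only, 352.2251 Da at 1.30 ± 0.168, and a second, 352.2252 Da, that went from 1.55 ± 0.245 to 2.55 ± 0.511 (adjusted p = 0.0088) but did not pass on the calibrant scale (adjusted p = 0.189).

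The 3 largest rises by limma were 314.0326, 349.0020 and 350.0092 Da, each at 1105 ± 300.0 (SD, n = 4) in streptomycin samples and listed at 0 in untreated samples. Their values were equal and their spacings those of a proton and of hydrogen chloride, so the 3 rows may count 1 ion and matched no listed formula. As a group listed at 0 takes the value put in for 0, these rises and the falls below rank by intensity in the other group. Besides the linoleic acid match at 280.2395 Da, the largest falls were 265.3004 Da, at 752 ± 56.5 in untreated samples, and 293.3317 Da, at 269 ± 19.3. Both were listed at 0 in streptomycin samples. Each had a partner at the spacing of sodium for hydrogen that ran the other way: 287.2824 Da, the formula of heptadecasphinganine, went from 753 ± 56.6 to 1130 ± 35.5, and 315.3137 Da was listed in streptomycin samples only at 417 ± 12.6. The rise of 287.2824 Da did not pass on the calibrant scale (limma adjusted p = 0.208). The falls of 265.3004 and 293.3317 Da are therefore not read as losses of a compound. Both masses stay in the main counts of masses in untreated samples only and of lower calls. The mass of dihydrocaffeic or hydroxyphenyllactic acid, 182.0580 Da, was the only match among 15 formulas of aromatic amino acid products, at 0.303 ± 0.0602 and 0.444 ± 0.0553 (adjusted p = 0.0168), but it did not pass with the replicate block (adjusted p = 0.0612), after division by total intensity (adjusted p = 0.0661), on the calibrant scale (adjusted p = 0.475), with the first acquisition alone (adjusted p = 0.0728) or with undetected values at the 5th percentile (adjusted p = 0.224). No mass matched streptomycin, amino acids, carnitines and polyamines, or bacterial cell wall units, and hexaric acid and indoleacetic acid were not matched either. In the technical list, of 8 masses 3 were higher, 2 lower and 3 not past the test. For it camera gave an adjusted p = 0.771. Polyethylene glycol 6, at 282.1679 Da, went from 0.965 ± 0.351 to 3.02 ± 0.474 (SD, n = 4). Polyethylene glycol 10, at 458.2726 Da, went from 4.31 ± 0.958 to 2.45 ± 0.849 but did not pass on the median-ratio scale. Polyethylene glycol 8, at 370.2203 Da, was at 4.02 ± 0.552 in untreated samples only. A partner at the spacing of potassium for sodium, 386.1943 Da, was listed in streptomycin samples only. Plasticware masses thus also differed between the groups.

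Camera called 4 of the 14 lists with at least 3 matched masses: nucleosides, plant polyphenols and sugars as higher and unconjugated bile acids as lower. With an estimated correlation 0 lists passed. When each formula kept only its nearest mass 0 passed as well, with adjusted p between 0.0645 and 0.0787 for these 4.

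**Figure D3:**
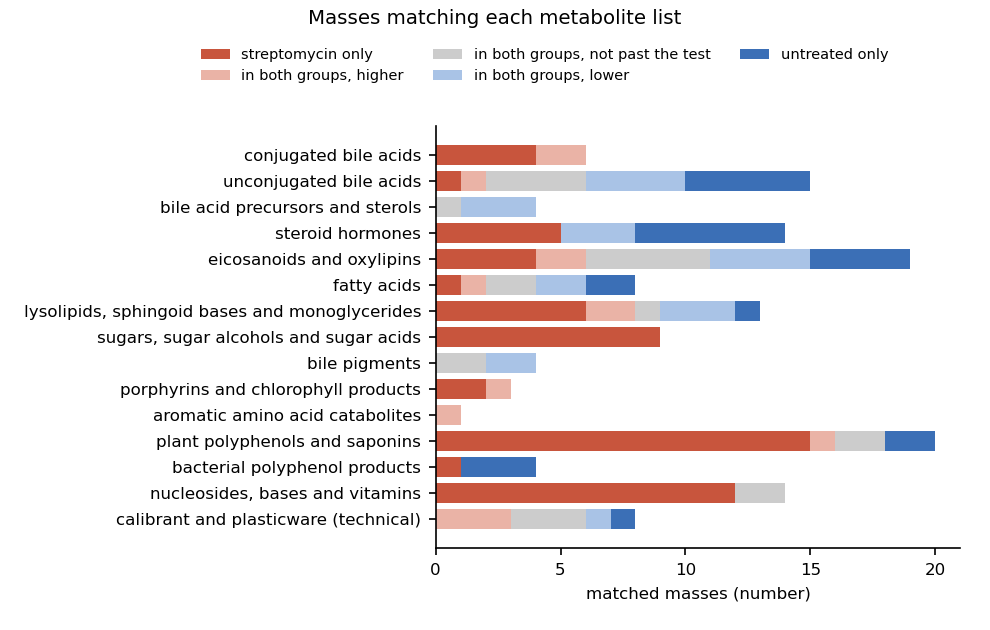
Number of masses (x axis) matching each metabolite list (y axis) within 3 ppm, divided into masses listed in streptomycin samples only, masses of both groups that were higher, not past limma's test or lower in streptomycin samples, and masses of untreated samples only. All 9 sugar masses are of streptomycin samples only, while 9 of 15 unconjugated bile acid masses are lower or of untreated samples only.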

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

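The test of equal acquisitions and its tolerances were chosen only after the result was seen. Of 84 groups of 4 values examined for a sample far from the others, 10 stood out because 1 value lay far outside the range of the other 3; chance alone marks about 1 in 20 groups, here 4.2.

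In streptomycin sample 1, 51.6% of the masses listed in both acquisitions had values within 0.0003 (log2) of each other, against 0.308% to 0.541% in the other streptomycin samples, and 382 masses had exactly equal values. If a spectrum of one ion mode had been deposited as both acquisitions, then of 2 rows of one mass, 1 from each mode, exactly 1 should have equal values, and this held for 100% of 101 such pairs, where 49.9% would arise if rows were equal at random. The share depends on the tolerance: it was also 100% at 0.001 log2 and 98.02% at 0.003, but 79.2% at 0.0001 and 38.6% for exact equality, near the 34.9% of equality at random. This is consistent with 1 spectrum standing in the table as both acquisitions of that sample, with small differences from rounding or rescaling that were not tested. The sample counts as 1 replicate either way, and without it 1969 masses were called in place of 2172. Leaving out another streptomycin sample gave 1945 to 2075, so a drop of this size is not particular to sample 1. No biological explanation was tested.

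The spread between acquisitions was 0.12 (log2 SD) in streptomycin sample 2 and 0.0973 to 0.1 in the other 3 streptomycin samples. Untreated sample 1 had 104 masses in a single acquisition, against 65 to 71 in the other untreated samples. The mass of mesoporphyrin, 566.2881 Da, was listed at 0 in streptomycin sample 4 and at 43.5 to 46.9 in the other 3. In the same sample dihydroxycholestanoic acid, 434.3397 Da, was at 1.73 against 2.92 to 3.08, and N-acetylhexosamine, 221.0900 Da, at 29.4 against 15.96 to 17.8. Streptomycin sample 3 had uridine, 244.0696 Da, at 5.58 against 7.21 to 7.52, and streptomycin sample 1 had trisaccharide, 504.1691 Da, at 16.7 against 11.9 to 12.7. Among untreated samples, sample 4 had prostaglandin E2 or D2, 352.2251 Da, at 1.05 against 1.37 to 1.40, and sample 2 had the weaker mass of cholic or muricholic acid, 408.2876 Da, at 19.8 against 12.3 to 13.2.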

How the results depend on the processing

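Scaling to the calibrants, the mean over listed acquisitions, merging of ion forms, the fit of masses in both groups alone, and the nearest-row and anion matches were chosen after seeing the data. The count of changed masses listed in both groups, 376, ran from 345 (116 higher, 229 lower, when these masses were fitted and adjusted alone) to 407 over all alternatives, and that over all masses, 2172, from 1925 to 2201 except with masses detected in all 8 samples, where 358 of 539 were called. The filter on detection removed no mass, so leaving it out changed nothing. The count of masses in one group only stayed at 1796 without each sample in turn, which the detection rule of at least 6 of 8 acquisitions fixes. Above the median intensity 837 masses were in one group only. At 4-fold, 75 masses passed (18 higher, 57 lower), and without each sample in turn the 2-fold count was 260 to 285. The differences in masses and in total intensity per sample kept their direction in all alternatives run; their permutation p stayed at the smallest value the sample numbers allow, so it cannot show how stable they are.

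Set tests depended most on the method: camera called 4 lists, 0 with an estimated correlation, 0 with the nearest mass per formula, and fry, which asks only whether a list's masses move one way on balance, called 14. The cause was not tested, and the nearest match keeps fewer masses in several lists. With sodium and chloride adducts also matched, conjugated bile acids had an adjusted p = 0.238 and unconjugated bile acids no longer passed (adjusted p = 0.0742), nor did the latter without streptomycin replicate 2 (adjusted p = 0.0532). Conjugated bile acids, just short of the threshold, passed under 6 other settings or left-out samples. These include fry, which called all 14 lists, and the anion masses (camera adjusted p = 0.0275). Of the added anion masses, 487.2372 Da has equal intensities to 488.2444 Da, already in the list, so the same ion may be counted again. No result changed direction past its threshold.

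Samples with the same number shared little: over 539 masses the correlations of their deviations from the group means were 0.03 to 0.124 (2 of 4 over 0.1), and 5 of 8 samples correlated best with their own number. With the replicate block 2171 masses, 375 of those in both groups and 4 lists were called. Masses missed in 1 or 2 acquisitions of a group had a median intensity of 0.930, against a median of 2.08 over all listed sample values.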

Other observations

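The formulas of isoflavone conjugates and soy cyclitols were looked up only after the values were seen, as were the tests of alignment, of splits for masses of one group, of isoflavone products of the calibrant scale by direction and of the median-ratio scale for the falls. Several masses of the streptomycin samples matched sulfates of soy isoflavones, conjugates made by the host, and those of genistein and daidzein were by far the more intense. The mass of genistein sulfate, 350.0092 Da, was at 1105 ± 300.0 (SD, n = 4) and that of daidzein sulfate, 334.0145 Da, at 912 ± 20.7, while glycitein sulfate, 364.0253 Da, was at 127 ± 19.5 and formononetin sulfate, 348.0305 Da, at 52.4 ± 10.6. All were listed at 0 in the 4 untreated samples. The genistein and daidzein sulfate masses each have partners at the spacings of a proton and of hydrogen chloride with equal intensities where both are listed (for 334.0145 Da, 333.0072 and 298.0378 Da), so other compounds are not ruled out. Malonyldaidzin and malonylgenistin, glucosides that plants store, were at 26.97 ± 7.74 (502.1111 Da) and 34.3 ± 10.9 (518.1061 Da), and the legume cyclitols pinitol and galactopinitol at 31.3 ± 6.32 (194.0790 Da) and 26.4 ± 7.16 (356.1319 Da), again in streptomycin samples only. A mass matching the anion of sulfated taurocholic or tauromuricholic acid, 594.2402 Da, was at 925 ± 212 in streptomycin samples, whereas the neutral mass, 595.2485 Da, was listed in untreated samples only, at 11.5, 0, 3.03 and 3.20.

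A hypothesis was that isoflavone parents and glucosides rose while their reduced bacterial products fell. All 10 changed masses of parents and glucosides were higher. Of 4 changed masses of reduced products 3 were lower, and 1, dihydrogenistein at 272.0687 Da, went against the hypothesis. With 1 exception among 4 the masses do not decide it, also since the mass of O-desmethylangolensin has a possible ion-form partner in streptomycin samples and the sulfates of equol (322.0512 Da, 2.95 ± 1.01) and dihydrodaidzein (336.0305 Da, 6.61 ± 0.937; SD, n = 4) were also listed in streptomycin samples only.

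The 1796 masses of one group only were weighed against 3 technical explanations. Merging rows that could be 1 ion listed under different neutral masses lowered their number by 15.3%. Only the spacings of a proton, sodium, potassium and hydrogen chloride were searched, so other ion forms stay open. Of the masses of one group only, 2.9% had a mass of the other group only within 3 ppm. Neither the ion forms as merged nor such a split of 1 mass accounts for most of them. Weak masses hidden by the detection rule of 6 of 8 acquisitions stay open: 87.8% of the masses of one group only were at or below 6.27, the 95th percentile of intensity of masses missed in 1 or 2 acquisitions, and 220 were above it. Splits of the 8 samples say nothing here, because the detection rule fixes the outcome: 1 of 35 splits, the real one, reached 1796, and the highest of the others was 151. Streptomycin itself, as the design names it, remains an untested explanation among the open ones.

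For masses in both groups, the real split gave 376 calls and the highest of the other 34 gave 0 (1 of 35 splits as large). This is the smallest share that 35 splits allow. The other splits mix the groups, which widens the spread on each side and favours few calls. Chance assignment of samples is unlikely only to that extent, and the samples may not be of different mice. For all masses (2172 against 0, 1 of 35) the splits say nothing more, since 1796 of the calls are masses of one group only. For ratios of at least 2, over the same masses, the real split gave 282 and the highest other 118; counted over masses listed on both sides of each split, others reached 1663, since masses of one group then enter.

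Scaling to the calibrants left the total of calls almost unmoved (a fall of -2.66%, that is a rise from 376 to 386), but this total trades one direction for the other and decides nothing. Of the 131 higher calls 49.6% kept their call, so for these a scale difference stays open. The calibrants rose (log2 change 0.42), and a scale difference of that sign cannot lower a mass, which argues against it for the 245 lower calls; that scaling keeps them follows from this and is no further test. A shift common to most masses would act the other way, and after division by the median ratio 72.2% of the lower calls were kept, so it stays open for the lower calls.

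For the 4 bile acid masses that fell and are listed in both groups, the median log2 change was -3.29. It was -2.89 after division by the median ratio, the one scaling that could shrink it. A common shift of the size the median ratio shows does not account for the fall of these 4. They were chosen because they fell, so this says nothing of the list as a whole. Over all 9 unconjugated bile acid masses listed in both groups the median log2 change was -0.71. After division by the median ratio 4 of these 9 were called lower and 2 higher. For the 4 masses that fell, the median was -3.71 on the calibrant scale, which could only deepen it once the calibrants had risen. Without the 10 most intense masses, and divided by the remaining total, it was -3.47. Streptomycin acting on bacteria that convert bile acids is a candidate explanation that these data do not test.

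For the 4 lists called by camera chance could not be excluded, as 6 of 35 splits gave at least 4 lists and the highest of the others gave 5. The splits that reach 4 or more keep 3 samples of each group together, and splits with 2 samples of each group on either side gave at most 2 lists. Of 30 pairs of rows within 1 ppm that were listed in both groups, 70% had the same sign of change (r = 0.42 across pairs, which are not independent replicates), so whether 2 rows of one mass report the same compound stays open. Of the masses of one group only, 64 (3.56%) lay within 0.05 Da of a mass at least 50 times as intense in the same group, against 11 (1.74%) of those in both groups.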
